A study of Mus musculus with 36 samples.

How the data were processed

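Total RNA from liver and kidney of 12-month-old male C57BL/6 mice was sequenced, in 18 libraries per tissue: 5 on the control diet, 6 on the high-fat diet and 7 on the ketogenic diet. Per the labels' protocols, cDNA was amplified from random and oligo-dT primers with the NuGEN Ovation RNA-Seq System V2, made into libraries with the Ovation Ultralow kit and sequenced on an Illumina HiSeq, with 18 barcoded samples pooled over 4 lanes. Which library ran in which pool is not stated in the labels, so no test by lane was made. Groups came from the sample titles and diet labels. Nothing in the labels says that a liver and a kidney library of the same title come from the same mouse.

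The authors deposited 1 table per tissue, each with raw counts per Ensembl gene, per the file headers. The kidney values are raw counts per the file headers, all whole, so no estimated counts had to be rounded. The liver counts were whole as well. Each table also holds the authors' log2 fold changes between the diets and the p-values or false discovery rates of their tests, per the file headers, and these were used only for comparison. The submitters' processing notes name TopHat2 2.0.11, Subread, featureCounts, edgeR and DESeq, with no role or order, and the genome build mm9. Another 90 columns of per-sample values, 54 for kidney and 36 for liver, hold other forms of the same data and were not used. Coordinates are the authors', in mm9. The liver table counts starts from 0: after adding 1, 77.8% of the 31501 genes in both tables have the same start, against 0.756% without, so 1 was added. A gene's start or end can differ between the tables, and the coordinates printed are those of the kidney table. The reference supplied for this work is of another build, GRCm38, and was not used. Neither labels nor headers state whether counting used strand, so a gene and an overlapping gene on the other strand cannot be told apart, and genes with near-identical copies are reported as uncertain.

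Counts were analysed in R 4.3.3. Genes were kept with edgeR 4.0.16 filterByExpr (minimum count 10, by diet), which left 13374 liver and 15074 kidney genes, and libraries were scaled by TMM factors. The main test was edgeR's robust quasi-likelihood F test with diet as the only term and all 18 libraries of a tissue in 1 fit, for each of the 3 pairs of diets. Tissues were fitted apart because they come in separate tables. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, at a threshold of 0.05. Standard errors are those of the log2 fold change. Counts per M use the same scaling, and log2 values add a prior count of 2. These tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise.

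The rule for named genes took, for each tissue and comparison, the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold with a mean log2 CPM of at least 2 and a proper symbol. It added up to 4 called members of each gene list with the smallest p, or, for a list described without a called member, the 2 members with the smallest p. In the comparison of ketogenic and control it also took, whatever their result, a set of genes fixed in advance that included Bdh1, Cpt1a, Pdk4, Fgf21, Ppargc1a, Cyp4a14, Srebf1, Fasn, Scd1, Pck1, Igfbp1, Foxo3 and Mt2.

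There were 43 gene lists. Those of metabolism covered ketone body metabolism, mitochondrial fatty acid oxidation, peroxisomal and omega oxidation, other PPAR alpha targets, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, bile acid and sterol export, glycolysis and fructose metabolism, gluconeogenesis and glycogen, amino acid catabolism and the urea cycle, the TCA cycle, oxidative phosphorylation, lipoproteins and lipid transport, and xenobiotic metabolism. Others covered insulin, IGF and FOXO genes, the integrated stress response, the unfolded protein response, heat shock, ribosomal proteins, Nrf2 and glutathione, the clock, acute phase and complement, interferon response, major urinary proteins, cell cycle, tubule injury and repair, renal acid-base genes, and renin, angiotensin and sodium genes. Marker lists covered hepatocytes, proximal tubule, loop to collecting duct, glomerulus, macrophages, lymphocytes, neutrophils, stellate cells and fibroblasts, endothelium, cholangiocytes, adipocytes, pancreatic acini, adrenal cortex, erythroid cells and skeletal muscle. Lists with at least 5 tested genes, 39 in each tissue, were tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry were alternatives. A list's score in a library is the mean deviation of its genes' log2 CPM from their mean over the tissue's libraries, and scores were compared by exact permutation of diet labels. Some lists overlap: Pck1, for example, is in 2, and the adipocyte markers Cidea and Fabp4 are also among the PPAR alpha targets. Camera compares a list with the other genes. Fry's directional and mixed tests do not.

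The fit was tested on counts simulated from the fitted means and dispersions of each tissue, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold between ketogenic and control. The changed genes were drawn from those with a mean log2 CPM of at least 2, and each gene was simulated independently of the others. In liver, on 13374 genes, it recovered 22.4% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 95.5% of those changed 4-fold, and 3 unchanged genes were called. In kidney, on 15074 genes, the shares were 62.7%, 95.5% and 100%, with 6 unchanged genes called. With no change simulated, 0 genes and 0 lists were called in either tissue. Because genes were simulated independently, the 0 lists cannot show how camera behaves on correlated genes. In kidney, other splits of the real ketogenic and control libraries called up to 22 lists at the preset correlation.

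Alternatives were DESeq2 1.42.0, limma-voom with sample weights, RLE factors or none in place of TMM, no low-count filter or a minimum count of 50, the 20 most abundant genes left out, only the 2 diets compared, the replicate number as a block, the kidney labels' sample number as a covariate, a threshold of 0.01, an absolute log2 change of at least 1, and each library left out in turn. Those added after the data were seen were 2 surrogate variables (sva 3.50.0) and the interferon list score as a covariate. Correlations between comparisons that share controls were set beside 20 simulations of unchanged groups and 20 splits of the controls. Up to 100 splits of the libraries of 2 diets into groups of the same sizes were refitted per comparison. Single libraries far from their group were found with Dixon's ratio, the gap to the nearest library over the group's range, at the 95% critical value. Precision rests on 7.17 to 14.6 M non-mitochondrial counts per liver library and 6.48 to 11.9 M per kidney library.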

Results

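RNA was sequenced from liver and kidney of 12-month-old male C57BL/6 mice after 1 of 3 diets: a control diet with 12% of its energy as fat, a high-fat diet that was not ketogenic with 75%, and a ketogenic diet with 90%, each with 10% as protein. Mice were habituated to the control diet and then kept on it or moved to another diet for 1 week, and tissue was taken at night, when mice feed. Each tissue had 5 control, 6 high-fat and 7 ketogenic libraries, 36 in all. Liver libraries held 18.9 to 35.9 M counts (26.8 ± 4.82 M, SD, n = 18) and kidney libraries 25.4 to 47.04 M (32.4 ± 5.23 M, SD, n = 18). Mitochondrial transcripts took 61.7% ± 5.38 of liver counts and 73.3% ± 2.73 of kidney counts (SD, n = 18), most of it mitochondrial ribosomal RNA, which left 7.17 to 14.6 M other counts per liver library and 6.48 to 11.9 M per kidney library. The mitochondrial share on the ketogenic and control diets was 64.2% ± 5.32 (n = 7) and 59.6% ± 6.77 (n = 5) in liver (two-sided exact permutation p = 0.215), and 73.8% ± 2.05 and 71.5% ± 2.42 in kidney (exact permutation p = 0.117). No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom between libraries of 1 diet was 27.2 in liver and 11.6 in kidney. The labels number the samples within a diet without stating that each is a separate mouse, and p-values measure the spread between these samples.

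In the kidney, 43 genes rose and 6 fell on the ketogenic diet against the control diet. Pdk4, the kinase that holds back pyruvate oxidation, rose 5.84-fold, from 6.24 ± 0.787 (SD, n = 5) to 36.4 ± 8.49 (SD, n = 7) CPM, counts per M after scaling by TMM factors. Angptl4, a secreted inhibitor of lipoprotein lipase, rose 3.64-fold, from 9.69 ± 1.59 to 35.3 ± 7.18 CPM. Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, rose 2.31-fold, from 310 ± 118 to 715.3 ± 106 CPM, while Scd1, the stearoyl-CoA desaturase, fell to 0.221 of its control level, from 90.9 ± 41 to 20.1 ± 7.23. All 7 ketogenic libraries lay above the control mean for Pdk4, Angptl4 and Pck1, and all 7 below it for Scd1. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, the log2 changes were 2.55 ± 0.16 (SE) for Pdk4 (adjusted p = 7.89e-11), 1.87 ± 0.17 for Angptl4 (adjusted p = 2.11e-07), 1.21 ± 0.23 for Pck1 (adjusted p = 0.0118) and -2.17 ± 0.33 for Scd1 (adjusted p = 0.00533). In mm9 coordinates these genes lie on chromosome 6 at 5433351 to 5446309 (Pdk4), 17 at 33910695 to 33918520 (Angptl4), 2 at 172978549 to 172984774 (Pck1) and 19 at 44468941 to 44482199 (Scd1).

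**Figure D1:**
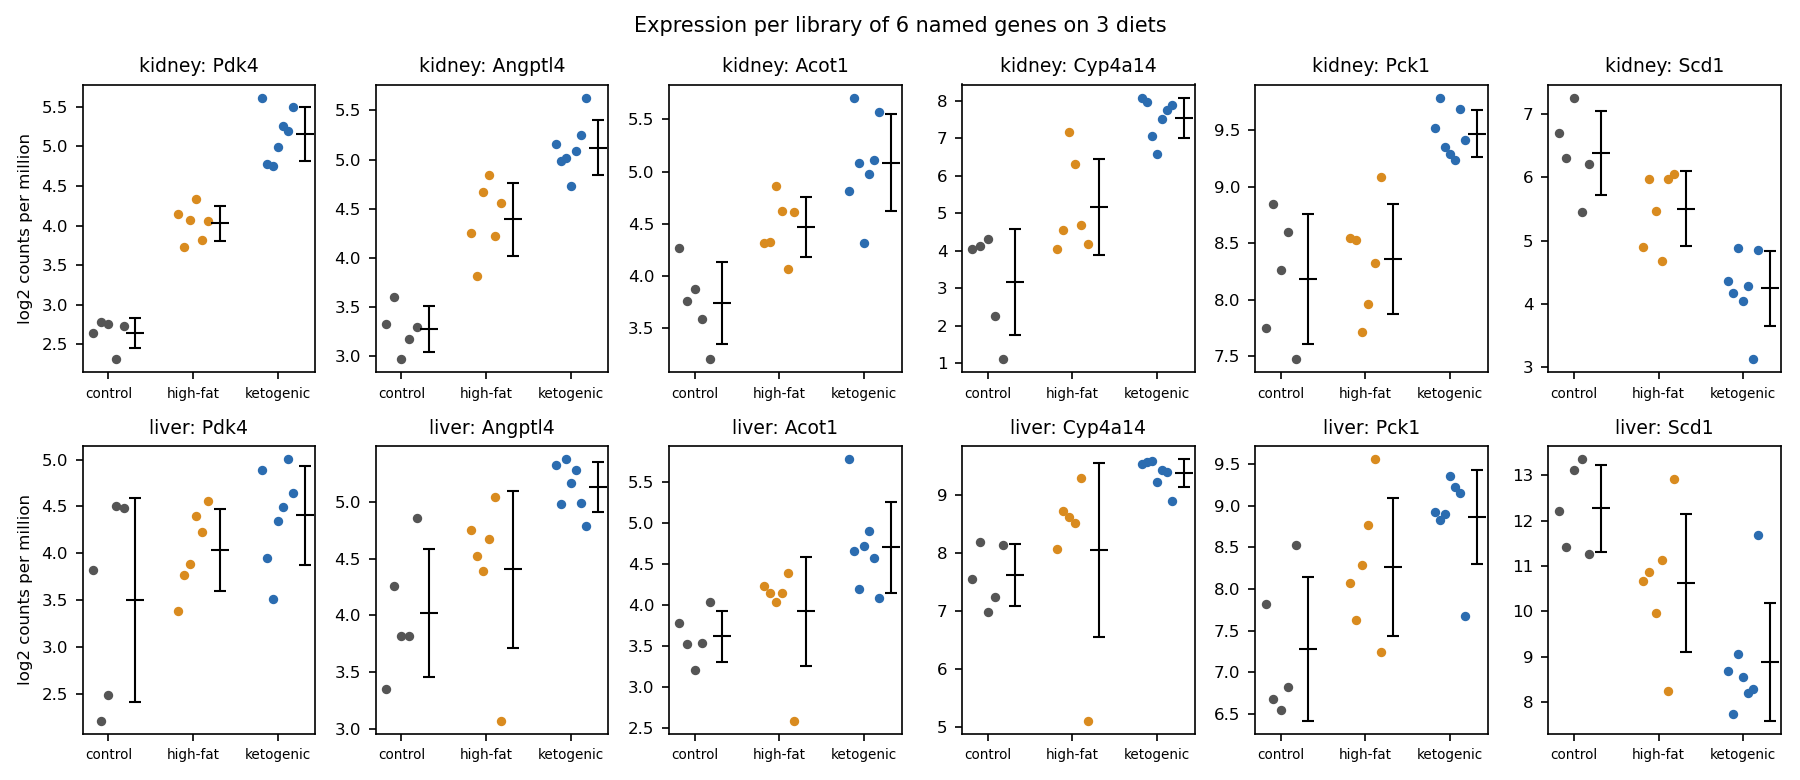
Expression of 6 genes on the 3 diets in kidney (top) and liver (bottom), as log2 CPM. Each point is 1 library, and the bar gives the mean ± SD. In kidney the 7 ketogenic libraries lie above the control mean for Pdk4, Angptl4, Acot1, Cyp4a14 and Pck1 and below it for Scd1. In liver 1 high-fat library lies far below the others for Angptl4, Acot1 and Cyp4a14.

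Targets of the fatty acid receptor PPAR alpha rose together in the ketogenic kidney. Of 21 measured genes in a list of such targets outside the oxidation pathways, 8 rose over all genes tested and 12 rose adjusted over the list alone, with a median log2 change of 0.57 (limma camera, adjusted p = 1.63e-15 with a preset and 0.00476 with an estimated correlation between genes, given below as preset and estimated). Besides Pdk4 and Angptl4 they included Ucp2, a mitochondrial uncoupling protein homolog (log2 change 1.09 ± 0.16, adjusted p = 0.000934), and Acot1, a cytosolic acyl-CoA thioesterase (1.36 ± 0.21, adjusted p = 0.00238), each higher in 7 of 7 libraries. Among 22 genes of peroxisomal and omega oxidation, 7 rose over all genes and 10 adjusted over the list alone, with a median of 0.43 (adjusted p = 4.88e-15 preset, adjusted p = 0.0114 estimated). Cyp4a14, a fatty acid omega-hydroxylase on chromosome 4 at 115158805 to 115168747, rose 16.3-fold, from 12.07 ± 8.06 to 197 ± 63.2 CPM (log2 change 4.02 ± 0.72, adjusted p = 0.0234). The peroxisomal thiolase Acaa1b (0.88 ± 0.14) and the peroxisome proliferation factor Pex11a (0.63 ± 0.10) rose at an adjusted p of 0.00238, as did the thioesterase Acot3 at 0.00746, and the Cyp4a relatives Cyp4a10, Cyp4a12b and Cyp4a31 rose by 1.40, 1.38 and 0.83 (adjusted p = 0.048, 0.0345 and 0.0228). These 3 lost their calls in 24, 12 and 11 of 32 alternative settings. Reads of the Cyp4a genes and of Acot1, Acot2 and Acot3 can be shared between near-identical copies, so the division among members is uncertain.

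Of 21 genes of mitochondrial fatty acid oxidation, 2 rose over all genes and 9 adjusted over the list alone, with a median of 0.32 (adjusted p = 8.85e-11 preset, adjusted p = 0.226 estimated). The 2 were the thioesterase Acot2 (1.01 ± 0.19, adjusted p = 0.0112) and the carnitine carrier Slc25a20 (0.72 ± 0.16, adjusted p = 0.0454), whose call was lost in 21 of 32 alternative settings. Cpt1a, the entry step, had 0.45 ± 0.16 (adjusted p = 0.379; 7 of 7 libraries above the control mean). Among 25 genes of fatty acid and triglyceride synthesis, 2 fell over all genes and 7 adjusted over the list alone, with a median of -0.14 (adjusted p = 0.000119 preset, adjusted p = 0.226 estimated): Scd1 and Mid1ip1, an activator of acetyl-CoA carboxylase (-0.78 ± 0.17, adjusted p = 0.0345). Fasn, the fatty acid synthase, had -1.09 ± 0.26 (adjusted p = 0.126) and Srebf1, its transcriptional regulator, -0.52 ± 0.14 (adjusted p = 0.136), each below the control mean in 7 of 7 libraries. Of 24 genes of cholesterol synthesis and uptake none passed over all genes and 6 fell adjusted over the list alone, with a median of -0.19 (adjusted p = 0.00011 preset, adjusted p = 0.226 estimated). Idi1 and Sqle had -0.74 ± 0.18 (adjusted p = 0.0893) and -0.44 ± 0.12 (adjusted p = 0.146). Of the 10 ketone body genes 0 passed over all genes and 2 rose adjusted over the list alone. This list's median was -0.06 and its mean 0.24 (adjusted p = 0.875).

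Pck1 was the 1 of 17 gluconeogenesis and glycogen genes and of 20 renal acid-base and ammonia genes to pass over all genes. 2 and 4 members rose adjusted over each list alone (list adjusted p = 0.764 and 0.144). Lipe, the hormone-sensitive lipase, rose by 0.75 ± 0.16 (adjusted p = 0.0345) while the adipocyte markers it belongs to had a median of -0.42 (adjusted p = 0.401). Besides Scd1 and Mid1ip1 the genes that fell included Slitrk6 (-1.14 ± 0.18, adjusted p = 0.00238), the interleukin-5 receptor gene Il5ra (-0.76 ± 0.16, adjusted p = 0.0239) and Tstd2 (-0.76 ± 0.17, adjusted p = 0.042). Lipe, Mid1ip1 and Tstd2 each lost their calls in 13 of 32 alternative settings, and Cyp4a14 and Pck1 in 7 and 6. Genes named in advance that did not pass were Igfbp1 (0.66 ± 0.38, adjusted p = 0.68), Mt2 (-0.19 ± 0.20, adjusted p = 0.851), and Foxo3, Ppargc1a and Bdh1, with log2 changes of -0.03, -0.0085 and -0.0080 and SEs of 0.15, 0.15 and 0.18. Fgf21 was not tested, with at most 2 counts in any library. Ribosomal protein genes (median -0.17, adjusted p = 0.00236 preset, adjusted p = 0.801 estimated) and lymphocyte markers (median -0.29, adjusted p = 0.0244 preset, adjusted p = 0.584 estimated) were lower in camera, with 0 members past the threshold in either list, as were loop, distal and collecting tubule markers (median -0.08, adjusted p = 0.0429 preset, adjusted p = 0.584 estimated).

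Of 15074 kidney genes tested, 1259 had an unadjusted p under 0.05 where 754 were due by chance. Leaving out control 3, control 0, control 4 or ketogenic 1 left 21, 24, 25 and 27 genes. DESeq2 called 105 genes and edgeR without normalization factors 18. The authors' deposited table called 8 genes in this comparison, 7 of them tested here, and all 7 were called here in the same direction.

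On the high-fat diet 2 kidney genes rose over control, both among those that rose on the ketogenic diet. Pdk4 rose 2.63-fold over control, to 16.4 ± 2.48 CPM (SD, n = 6; log2 change 1.40 ± 0.16, adjusted p = 2.98e-05), and Angptl4 2.22-fold, to 21.5 ± 5.28 (1.15 ± 0.17, adjusted p = 0.00238). All 6 libraries lay above the control mean for both. The other PPAR alpha targets were higher as a list, with a median of 0.31 and 6 of 21 genes up adjusted over the list alone (adjusted p = 4.91e-06 preset, adjusted p = 0.259 estimated). Peroxisomal and omega oxidation had a median of 0.23, 1 of 22 genes up adjusted over the list alone and the same adjusted p of 4.91e-06 (adjusted p = 0.284 with an estimated correlation). Cyp4a12b had 1.35 ± 0.28 (adjusted p = 0.241) and Cyp4a14 2.09 ± 0.67 (adjusted p = 0.628, 1.43 without high-fat 2), each above the control mean in 6 of 6 libraries. Mitochondrial fatty acid oxidation had a median of 0.13 with 0 of 21 genes passing (adjusted p = 0.000325 preset, adjusted p = 0.74 estimated), with Acot2 at 0.61 ± 0.19 (adjusted p = 0.573) and Slc25a20 at 0.44 ± 0.16 (adjusted p = 0.749).

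Interferon response genes were higher in the high-fat kidney as a list, with a median of 0.38 and 0 of 26 passing (adjusted p = 0.000325 preset, adjusted p = 0.74 estimated). Cxcl10 had 0.60 ± 0.22 and Mx2 1.09 ± 0.53, or 0.36 without high-fat 2. The list's score was highest in high-fat 2 (1.37), control 0 (0.909) and high-fat 3 (0.65), with the next library at 0.022. Cell cycle genes had a median of 0.23, 2 of 23 up adjusted over the list alone (adjusted p = 0.0148 preset, adjusted p = 0.74 estimated), with Top2a at 0.86 ± 0.23 and Mki67 at 0.87 ± 0.24, above the control mean in 6 of 6 libraries. Acute phase and complement genes had a median of 0.46 (adjusted p = 0.0367 preset, adjusted p = 0.463 estimated), and ribosomal protein genes -0.21 with 0 of 41 passing (adjusted p = 1.03e-05 preset, adjusted p = 0.74 estimated). Exact permutation of list scores, adjusted over 38 lists, gave an adjusted p of 0.715 for interferon response and 0.124 for cell cycle. It gave 0.0548 for acute phase and complement and 0.79 for ribosomal proteins. In all, 864 genes had an unadjusted p under 0.05 where 754 were due by chance, and DESeq2 called 15. The authors' deposited table called 1 gene, which was not among those tested here.

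Set against each other, the ketogenic and high-fat diets differed in kidney at 7 genes, with Pdk4 2.22-fold higher on the ketogenic diet (log2 change 1.15 ± 0.14, adjusted p = 0.000121). Transporters and a brush border gene of the tubule were higher: Slc5a10, a sodium-coupled sugar transporter on chromosome 11 at 61486283 to 61534328, averaged 31.4 ± 4.93 (n = 7) against 19.6 ± 1.27 (n = 6) CPM (0.68 ± 0.12, adjusted p = 0.0131). Slc13a2, a sodium-coupled citrate and dicarboxylate transporter, rose by 0.68 ± 0.13 and the brush border cadherin Cdhr2 by 0.63 ± 0.12, both at an adjusted p of 0.0467. Calb1, the calcium-binding calbindin of the distal tubule on chromosome 4 at 15808411 to 15835211, was lower, at 43.4 ± 7.01 against 76.3 ± 13.2 (-0.81 ± 0.16, adjusted p = 0.0467), as was Il5ra (-0.90 ± 0.15, adjusted p = 0.0131). Each of these held its direction in 7 of 7 ketogenic libraries against the high-fat mean. The calls of Slc13a2, Cdhr2 and Calb1 were lost in 22, 23 and 20 of 32 alternative settings, in none of which their direction turned. The fifth rise was Mogat2, outside the rule for named genes and named after its values were seen.

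The other PPAR alpha targets were higher on the ketogenic than on the high-fat diet: 1 of 21 rose over all genes and 10 adjusted over the list alone, with a median of 0.44 (adjusted p = 3.05e-11 preset, adjusted p = 0.0212 estimated). Peroxisomal and omega oxidation had 7 of 22 up adjusted over the list alone, with a median of 0.22 (adjusted p = 7.14e-07 preset, adjusted p = 0.112 estimated). Acaa1b had 0.65 ± 0.13 (adjusted p = 0.0903) and Acot3 0.84 ± 0.21 (adjusted p = 0.293). Mitochondrial fatty acid oxidation had a median of 0.17 with 0 of 21 passing (adjusted p = 3.08e-05 preset, adjusted p = 0.362 estimated). Inflammatory and injury lists were lower with 0 members past the threshold over all genes. Interferon response genes had a median of -0.57, all 26 below 0 (adjusted p = 1.25e-08 preset, adjusted p = 0.362 estimated), with Usp18 at -0.81 ± 0.27 and Mx2 at -1.19 ± 0.49, or -0.46 without high-fat 2. High-fat 2 and high-fat 3 carried interferon scores of 1.37 and 0.65. Tubule injury and repair genes had a median of -0.39 (adjusted p = 1.01e-06 preset, adjusted p = 0.112 estimated), with the injury marker Clu at -0.52 ± 0.19 and the chemokine Ccl2 at -0.86 ± 0.32. Acute phase and complement genes had a median of -0.19, 2 of 13 down adjusted over the list alone (adjusted p = 0.000307 preset, adjusted p = 0.0548 estimated), with C4b at -0.90 ± 0.21 (adjusted p = 0.157) and Serpina3n at -1.77 ± 0.56 (adjusted p = 0.639). Macrophage markers had -0.19 (adjusted p = 3.08e-05 preset, adjusted p = 0.137 estimated) and adipocyte markers -0.89 (adjusted p = 0.000743 preset, adjusted p = 0.362 estimated). With exact permutation of list scores, adjusted p was 0.266 for interferon response, 0.0849 for tubule injury and repair and 0.0445 for acute phase and complement. It was 0.0885 for macrophage and 0.221 for adipocyte markers.

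In this comparison 5 genes rose and 2 fell, 613 had an unadjusted p under 0.05 where 754 were due by chance, and DESeq2 called 30. The authors' deposited table called 0. The count fell to 2 without high-fat 1, to 3 without high-fat 0, and to 4 without each of control 0, control 2, high-fat 4, ketogenic 0, ketogenic 4 and ketogenic 6, with limma-voom at 4.

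In the liver, lists of lipid genes differed between the ketogenic and control diets, while no single gene passed the test. The number of lists past the threshold was 16 with the preset and 0 with an estimated correlation. Scd1 averaged 775 ± 1110 (SD, n = 7) CPM against 5894 ± 3670 (SD, n = 5) on the control diet (log2 change -2.93 ± 0.79), and Fasn 91.7 ± 67.2 against 438 ± 286 (-2.25 ± 0.55). Elovl6, which elongates fatty acids, averaged 50.9 ± 23.3 against 289 ± 220 (-2.50 ± 0.53), and Srebf1 36.9 ± 3.47 against 66.2 ± 23.2 (-0.84 ± 0.19). Cyp4a14 averaged 674 ± 104 against 208 ± 75.3 (1.70 ± 0.42) and Cpt1a 72.3 ± 9.93 against 42.2 ± 12 (0.78 ± 0.19). All 7 ketogenic libraries lay on the same side of the control mean for each, and the adjusted p was 0.26 for Scd1 and 0.224 for the other 5. Ketogenic 6 had a log2 CPM of 11.7 for Scd1 against a mean of 8.42 in the other ketogenic libraries, and without it the log2 change of Scd1 was -4.05 (adjusted p = 0.0281).

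Among 26 liver genes of fatty acid and triglyceride synthesis 17 fell adjusted over the list alone, with a median of -0.90 (adjusted p = 5.66e-13 preset, adjusted p = 0.215 estimated). Mid1ip1 had -1.24 ± 0.26 (adjusted p = 0.224). Among 24 other PPAR alpha targets 15 rose adjusted over the list alone, with a median of 0.67 (adjusted p = 5.14e-14 preset, adjusted p = 0.215 estimated), with Acot1 at 1.16 ± 0.28 and Angptl4 at 1.04 ± 0.26. Of 22 genes of peroxisomal and omega oxidation 14 rose adjusted over the list alone, with a median of 0.51 (adjusted p = 6.76e-12 preset, adjusted p = 0.215 estimated), with Cyp4a10 at 1.25 ± 0.34. Of 21 genes of mitochondrial fatty acid oxidation 12 rose adjusted over the list alone, with a median of 0.45 (adjusted p = 5.14e-14 preset, adjusted p = 0.215 estimated), with Acsl1, the acyl-CoA synthetase, at 0.82 ± 0.19. The 9 genes of ketone body metabolism had a median of 0.33 with 0 passing (adjusted p = 0.00626 preset, adjusted p = 0.452 estimated). Bdh1 had 0.69 ± 0.25 (adjusted p = 0.392) and the monocarboxylate carrier Slc16a1 0.42 ± 0.16 (adjusted p = 0.434). Of these lists, fry's directional test passed for mitochondrial oxidation, peroxisomal oxidation and the PPAR alpha targets, each at an adjusted p of 0.0414, and gave 0.0669 for fatty acid synthesis.

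Of 24 liver genes of cholesterol synthesis and uptake 9 rose adjusted over the list alone, with a median of 0.16 (adjusted p = 4.42e-05 preset, adjusted p = 0.452 estimated). Cyp51 had 0.78 ± 0.21 and Hsd17b7 0.84 ± 0.22. Glycolysis and fructose genes had 4 of 25 down adjusted over the list alone, with a median of -0.14 (adjusted p = 0.0185 preset, adjusted p = 0.452 estimated), with Pklr, the liver pyruvate kinase, at -1.59 ± 0.38 (adjusted p = 0.224). Gluconeogenesis and glycogen genes moved both ways, 2 up and 4 down adjusted over the list alone, with a median of -0.10 (adjusted p = 0.239): Pck1 averaged 491 ± 146 against 181 ± 118 CPM (1.44 ± 0.41, adjusted p = 0.272), the glycogen phosphorylase Pygl had -0.95 ± 0.18 and the glycogen-targeting subunit Ppp1r3b -0.91 ± 0.20. Bile acid genes had a median of 0.10 (adjusted p = 0.0401 preset, adjusted p = 0.494 estimated), with the phospholipid exporter Abcb4 at 0.75 ± 0.18 and Cyp8b1 at 0.83 ± 0.32. Clock genes had -0.16 (adjusted p = 0.0401 preset, adjusted p = 0.452 estimated), with Bhlhe40 at -0.85 ± 0.23, and amino acid catabolism 0.11 (adjusted p = 0.00582 preset, adjusted p = 0.494 estimated), with Agxt at 0.78 ± 0.21 and Gldc at 0.60 ± 0.18. Ribosomal protein genes had -0.41, all 41 below 0 and 0 passing (adjusted p = 1.06e-09 preset, adjusted p = 0.494 estimated). Control 0 and control 1 carried scores of 1.09 and 0.908 for this list. Exact permutation of its scores between the diets gave an adjusted p of 0.612. Markers of other cells were higher for adipocytes (median 0.39, adjusted p = 0.00102 preset, adjusted p = 0.253 estimated), erythroid cells (0.47, adjusted p = 0.00966 preset, adjusted p = 0.452 estimated) and lymphocytes (0.43, adjusted p = 0.0401 preset, adjusted p = 0.452 estimated), while hepatocyte markers had -0.04 (adjusted p = 0.609). Other genes named in advance were Pdk4 (0.68 ± 0.35, adjusted p = 0.578), Fgf21 (0.30 ± 0.53, adjusted p = 0.903, 1.15 without control 0), Ppargc1a (-0.40 ± 0.18, adjusted p = 0.492), Mt2 (-1.40 ± 0.55, adjusted p = 0.432, -0.72 without control 0 and -2.05 without ketogenic 5), Igfbp1 (0.14 ± 0.52, adjusted p = 0.96) and Foxo3 (-0.07 ± 0.12, adjusted p = 0.905).

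**Figure D2:**
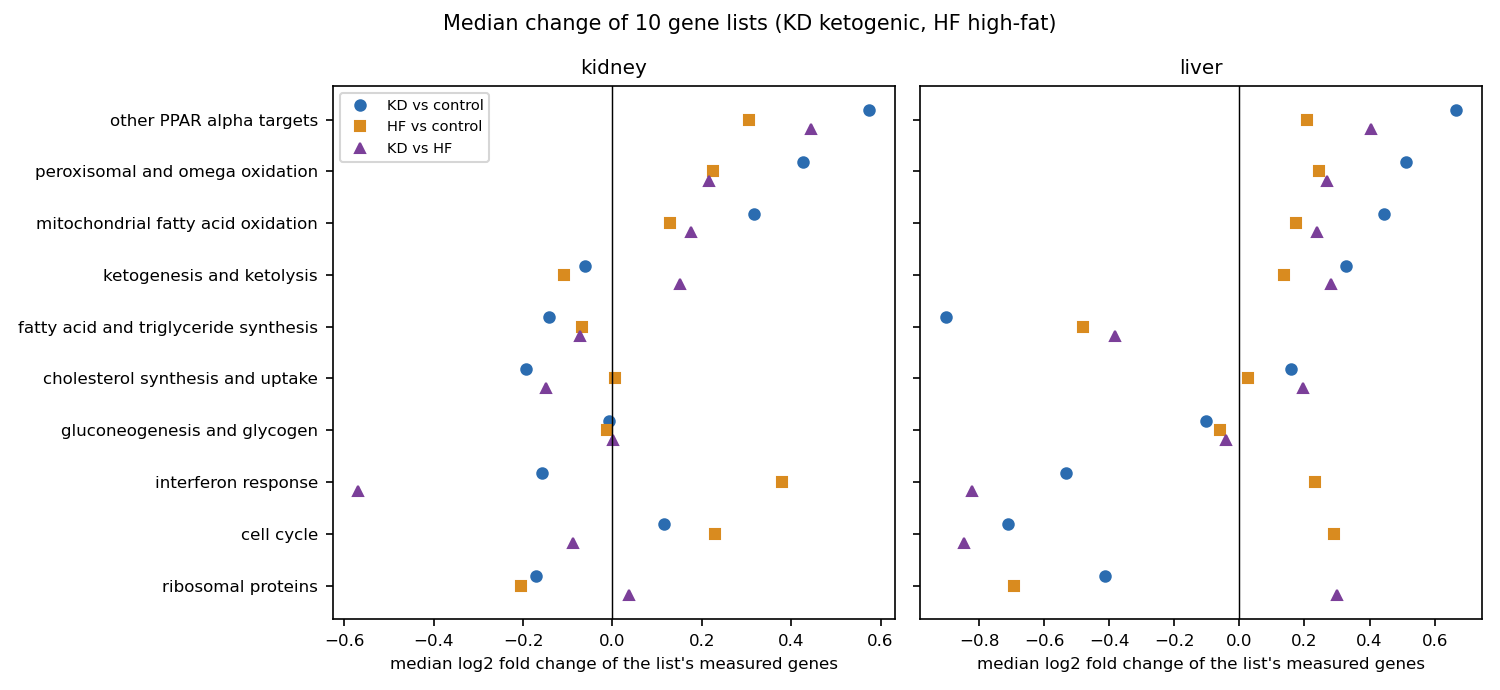
Median log2 fold change of the measured genes of 10 lists in kidney (left) and liver (right). Circles give ketogenic over control, squares high-fat over control and triangles ketogenic over high-fat. The 3 lists of fatty acid oxidation and PPAR alpha targets lie above 0 in every comparison, and fatty acid and triglyceride synthesis lies below 0 in each.

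With edgeR 0 of 13374 liver genes passed between ketogenic and control (smallest adjusted p = 0.224), though 1255 had an unadjusted p under 0.05 where 669 were due by chance. DESeq2 called 76, 42 up and 34 down, limma-voom 0, and edgeR with 2 surrogate variables 2. With the replicate number as a block, edgeR called 52 genes up and 29 down. The labels do not tie these numbers to animals, so the block was not in the main fit. Without control 4, high-fat 5 or ketogenic 6, edgeR called 22, 14 and 2. Control 0 stood apart from the other libraries: its SD from the mean of its own diet was 1.31 log2 units, against 0.402 to 0.792 in the other 17. The authors' deposited table called 231 genes in this comparison, of which 175 were tested here. 157 had the same direction, 145 an unadjusted p under 0.05 here, and the fold changes of the tables correlated across genes at r = 0.807.

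On the high-fat diet the liver's fatty acid and triglyceride synthesis genes were lower than on the control diet as a list, with 2 of 26 down adjusted over the list alone and a median of -0.48 (adjusted p = 6.52e-06 preset, adjusted p = 0.762 estimated). Mid1ip1 had -0.92 ± 0.27 and Elovl6 -1.81 ± 0.54 (-2.46 without high-fat 5), each below the control mean in 6 of 6 libraries (adjusted p = 0.681 for both). Mitochondrial fatty acid oxidation had a median of 0.17 (adjusted p = 0.00242 preset, adjusted p = 0.762 estimated) and peroxisomal and omega oxidation 0.24, all 22 above 0 (adjusted p = 0.0147 preset, adjusted p = 0.762 estimated), with 0 members passing. Cpt1a had 0.59 ± 0.19 and Acsl1 0.49 ± 0.19, each higher in 5 of 6 libraries. The other PPAR alpha targets had 0.21 (adjusted p = 0.0521). Ribosomal protein genes had -0.69, all 41 below 0 and 0 passing (adjusted p = 1.43e-16 preset, adjusted p = 0.762 estimated), with Rps7 at -0.80 ± 0.29 and Rpl13 at -0.72 ± 0.27. Reads of these genes can be shared with their pseudogenes. Oxidative phosphorylation genes had -0.34 (adjusted p = 6.68e-06 preset, adjusted p = 0.762 estimated). By exact permutation of list scores, adjusted p was 0.646 for fatty acid and triglyceride synthesis, 0.646 for ribosomal proteins and 0.716 for oxidative phosphorylation. Control 0 and control 1 scored 1.09 and 0.908 for ribosomal protein genes, against -0.379 to 0.221 in the other controls, and 0.43 and 0.416 for oxidative phosphorylation, against -0.39 to 0.191. With edgeR 0 genes passed (smallest adjusted p = 0.217), 950 had an unadjusted p under 0.05 where 669 were due by chance, DESeq2 called 1, limma-voom 0, and edgeR without control 4 called 1. The number of lists past the threshold was 9, and rose to 18 without control 0 and 22 without high-fat 5. The authors' deposited table called 87 genes, 53 of them tested here, 49 in the same direction.

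Between the ketogenic and high-fat diets, 18 lists passed in liver with the preset and 0 with an estimated correlation, and 0 genes passed. The other PPAR alpha targets had a median of 0.40 and 2 of 24 up adjusted over the list alone (adjusted p = 9.51e-13 preset, adjusted p = 0.487 estimated): G0s2, an inhibitor of triglyceride lipase, averaged 81.3 ± 18.8 against 34.6 ± 14.7 CPM (1.23 ± 0.30), and Txnip had 0.52 ± 0.14, each above the high-fat mean in 7 of 7 libraries. Mitochondrial fatty acid oxidation had 0.24, all 21 above 0 (adjusted p = 3.68e-09 preset, adjusted p = 0.652 estimated), with the carnitine transporter Slc22a5 at 0.67 ± 0.25 and Eci2 at 0.45 ± 0.18. Peroxisomal and omega oxidation had 0.27 (adjusted p = 2.68e-08 preset, adjusted p = 0.652 estimated), with Pex11a at 0.68 ± 0.22 and Cyp4a10 at 0.83 ± 0.31, and fatty acid and triglyceride synthesis -0.38 (adjusted p = 0.000161 preset, adjusted p = 0.652 estimated). Cell cycle genes had -0.84 (adjusted p = 1.74e-06 preset, adjusted p = 0.652 estimated), with Rrm2 at -1.73 ± 0.52 and Cdk1 at -2.30 ± 0.77, and interferon response genes -0.82, all 27 below 0 (adjusted p = 1.57e-05 preset, adjusted p = 0.704 estimated), with Oasl2 at -1.01 ± 0.39 and Ifi44 at -1.61 ± 0.63. Without high-fat 2 Ifi44 had -0.80 and Cdk1 -1.61. Exact permutation of the cell cycle and interferon list scores gave an adjusted p of 0.661 for each. High-fat 2 and high-fat 3 carried the highest scores of these lists among libraries of these diets, 1.82 and 1.48 for cell cycle and 1.68 and 1.18 for interferon. With edgeR no gene passed (smallest adjusted p = 0.999), 426 had an unadjusted p under 0.05 where 669 were due by chance, DESeq2 called 1 and limma-voom 0. 18 lists passed, and 10 without high-fat 2. The authors' deposited table called 226 genes, 199 of them tested here, all 199 in the same direction and 98 with an unadjusted p under 0.05.

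Both diets were compared with the same control libraries, which ties their fold changes together. Across 15074 kidney genes the log2 changes on the ketogenic and high-fat diets correlated at r = 0.668, with a mean of 0.559 in 20 simulations of unchanged groups against those controls. The covariance was 0.0551 against a simulated 0.0339, and 74.1% of genes had the same sign against 69%. With the controls split into separate parts the mean correlation was 0.213 (0.0438 to 0.307 over 20 splits). Pdk4 and Angptl4 rose on both diets, where 0.00571 shared genes were due for independent lists, a number that leaves out the shared controls. The simulations hold no effects and shared at most 0 called genes, which decides nothing here. Across 13374 liver genes the correlation was 0.705 against a simulated 0.566, the covariance 0.119 against 0.0693, and the same sign 75.8% against 69.1%. With split controls the liver correlation was -0.0153 (-0.162 to 0.188). Genes are not independent replicates.

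Changes on the ketogenic diet correlated between tissues at r = 0.169 and Spearman's rho = 0.177 across the 12414 genes tested in both. The value was 0.0576 without liver control 0 and 0.44 over genes with a mean log2 CPM of at least 4. It was 0.68 over genes called in at least 1 tissue. As liver had 0 called genes, these are the genes picked for their change in kidney, which can raise the correlation. Of 42 genes called in kidney and tested in liver, 36 had the same direction in liver and 25 of those also an unadjusted p under 0.05. The like shares over all 12414 genes are not given here for comparison. The mean list scores of both tissues were compared by exact permutation of the diet labels, two-sided, over 38 lists. The other PPAR alpha targets were higher by 0.779 in liver (exact p = 0.00126, adjusted p = 0.016) and 0.712 in kidney (exact p = 0.00126, adjusted p = 0.0239), above the control mean in 7 of 7 ketogenic libraries of each tissue. 0.00126 is the smallest p these groups allow. Peroxisomal and omega oxidation was higher by 0.655 and 0.687 at the same p-values. Fatty acid and triglyceride synthesis was lower, at -0.941 in liver and -0.299 in kidney (adjusted p = 0.048 in each). In liver mitochondrial fatty acid oxidation (0.562, adjusted p = 0.016), renal acid-base genes (0.358, adjusted p = 0.024) and adipocyte markers (1.32, adjusted p = 0.0288) passed, and in kidney these had adjusted p-values of 0.135, 0.546 and 0.653. The adipocyte markers, which share Cidea and Fabp4 with the PPAR alpha targets, scored lowest in liver control 0 and control 2 (-2.24 and -1.45), and their difference between the tissues was 1.72 (adjusted p = 0.0745). The difference between the tissues was tested by permuting the labels within each tissue. This takes diet to have no effect in either tissue and treats the tissues as independent. Cholesterol synthesis and uptake, the 1 of 38 lists that passed, changed on the ketogenic diet by 0.325 in liver and -0.214 in kidney. The difference was 0.538 (permutation p = 0.00105, adjusted p = 0.0397). Within each tissue its change did not pass (exact permutation adjusted p = 0.112 in liver and 0.135 in kidney).

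**Figure D3:**
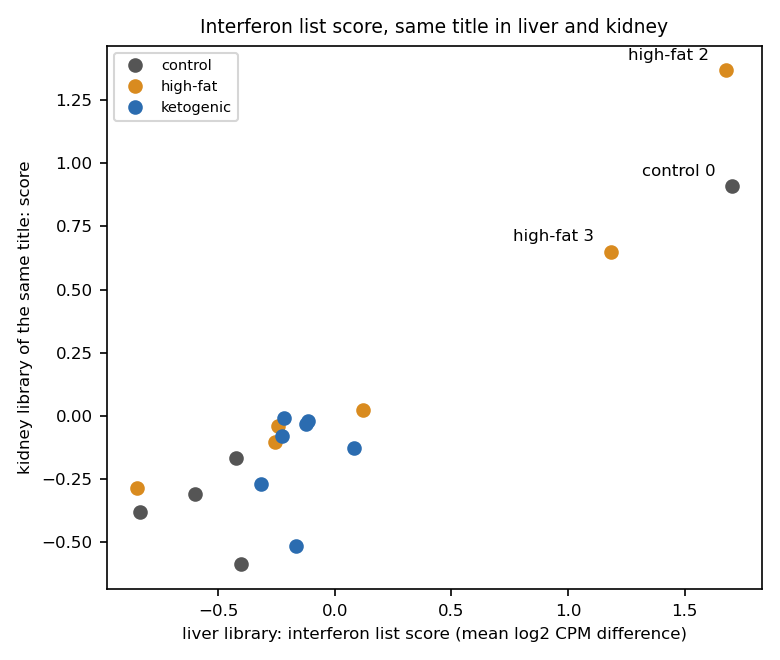
Interferon list score of each liver library (horizontal) against the kidney library of the same title (vertical), in mean log2 CPM from the tissue mean. Each of the 18 points is 1 title, coloured by diet. Control 0, high-fat 2 and high-fat 3 lie apart from the other 15 in both tissues.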

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

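The rules that picked single libraries and differences between tissues were set beforehand. The tests of explanations for the 3 patterns below were chosen only after the results were seen. Dixon's ratio passed its critical value in 18 of 276 groups, where chance picks about 1 in 20, or 14.

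The interferon list stood out in 3 titles in both tissues: it scored 1.70 in liver control 0, 1.68 in high-fat 2 and 1.18 in high-fat 3, with the next liver library at 0.121, and the kidney libraries of the same titles were the 3 highest there (0.909, 1.37 and 0.65; next 0.022). In liver, the deepest and shallowest libraries scored -0.112 at most, which argues against depth as the source there. The lymphocyte marker scores of the 3 liver libraries (median 0.246, others up to 0.975) argue against lymphocytes there. Neither was tested in kidney, and both stay open there. Kidney high-fat 2 was the deepest without mitochondrial counts (11.9 M), with control 0 at 10.7 M and high-fat 3 at 6.97 M. Their lymphocyte scores were 0.04, 0.868 and 0.041, that of control 0 being the highest in kidney. The major urinary proteins were low in the 3 liver libraries (-1.86, -2.47 and -1.27). A median hepatocyte marker score of -0.176 argues against dilution by other cells for that fall, not for the interferon scores. The overlap of titles (exact p = 0.00123, one-sided, the smallest possible) is consistent with a state shared by an animal's organs, such as an infection, but the labels do not tie titles to animals, and over 6364 genes libraries of the same title did not resemble each other (mean r = -0.041; best match in 1 of 18). Macrophage markers (1.03, 0.521 and 0.382 in the 3 liver libraries, others up to 0.419) stay open, and no group of the design separates these libraries.

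PPAR alpha targets were higher in the ketogenic kidney, at a median log2 change of 0.57. A larger share of proximal tubule in the samples would raise the tubule's markers by a like amount, but their median change was 0.0967. A few abundant genes distorting the scaling is argued against by the 43 genes called with the 20 most abundant left out, all 43 among the 49 called with them. A response of the tissue to the ketogenic diet stays open as the biological explanation, which these tests did not address further.

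Liver ribosomal protein scores were higher on average in libraries numbered 0 and 1 than in the others of their diet. On high-fat, however, library 3 (0.0085) lay above both 0 (-0.118) and 1 (0.0025). The grouping was chosen after the scores were seen, so the p-value below is not an independent test of it. The mean difference was 0.772 within diets (two-sided exact permutation p = 0.000952 over 3150 arrangements), with means of 1.0 against -0.11 on control, -0.0577 against -0.296 on high-fat and 0.637 against -0.329 on ketogenic. In kidney the difference was -0.582. This is consistent with liver libraries 0 and 1 having been handled apart, though the labels give no batch, the pattern was found in the same data, and a biological difference between those mice was not tested. Ribosomal protein changes between diets in liver can carry this difference.

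Liver high-fat 5 was lowest of its diet for Slc22a5 (Dixon ratio 0.649), Acot1 (0.807), Angptl4 (0.67) and Cyp4a14 (0.709) and highest for Fasn (0.736) and Ppp1r3b (0.703). Liver ketogenic 6 was lowest for Cyp4a10 (0.648) and Pck1 (0.684) and highest for Rrm2 (0.634), Fasn (0.651) and Scd1 (0.667). Liver control 0 was highest of the controls for Ifi44 (0.716), liver control 2 lowest for Igfbp1 (0.749) and liver ketogenic 5 highest for Mt2 (0.712). In kidney, control 4 was lowest for Acaa1b (0.721), ketogenic 1 highest for Calb1 (0.658), and high-fat 3 lowest for Lipe (0.656) and Srebf1 (0.658).

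Cholesterol synthesis and uptake was flagged for its change on the ketogenic diet, with list scores 0.538 further up in liver than in kidney (permutation adjusted p = 0.0397). The permutation takes diet to have no effect in either tissue, so it does not test whether the changes of the tissues are equal. Neither tissue's own change passed (exact permutation adjusted p = 0.112 in liver and 0.135 in kidney). Of its genes, Idi1 was above the control mean in every ketogenic liver library (mean log2 difference 0.921) and below it in every ketogenic kidney library (-0.711), a gap of 1.63, and Sqle likewise (0.51 and -0.45, a gap of 0.96). Cyp51 had mean log2 differences of 0.785 in liver and -0.432 in kidney, and Hsd17b7 0.902 and 0.0424. The difference between tissues was not tested for any of these genes.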

How the results depend on the processing

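The alternatives with 2 surrogate variables and with the interferon score as a covariate were chosen after seeing the data. All others were set before. The cause of a change was not tested unless stated. For ketogenic against control in liver, edgeR's 0 genes became 76 with DESeq2, 4 with only the 2 diets compared, 2 with surrogate variables and 2 with the interferon score. In liver, high-fat against control gave 1 with DESeq2 and 1 with surrogate variables, and ketogenic against high-fat 1 with DESeq2. For ketogenic against control in kidney, 49 genes (43 up, 6 down) became 105 with DESeq2 (82 up, 23 down), 112 with surrogate variables (104 up, 8 down), 75 with limma-voom, 18 without normalization factors (12 up, 6 down), and, by construction, 21 at an adjusted p of 0.01 and 25 at an absolute log2 change of at least 1. High-fat against control in kidney (2 genes) gave 15 with DESeq2 (9 up, 6 down) and 20 with surrogate variables (15 up, 5 down). Ketogenic against high-fat in kidney (7 genes, 5 up, 2 down) gave 30 with DESeq2 (17 up, 13 down), 25 with surrogate variables (15 up, 10 down), 3 without normalization factors, 4 with limma-voom, 1 at 0.01 and 2 at an absolute log2 change of at least 1. Leaving out normalization factors shifted the median log2 change of all genes to -0.127 in liver for ketogenic against control, -0.171 for ketogenic against high-fat, and -0.108 in kidney for high-fat against control.

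Lists past the threshold went from 16, 9 and 18 in liver (ketogenic and high-fat against control, ketogenic against high-fat) to 0 in each with an estimated correlation and to 3, 0 and 0 with fry's directional test. In kidney they went from 12, 12 and 15 to 2, 0 and 1 with an estimated correlation and 3, 1 and 1 with fry's directional test. Fry's mixed test called 9, 0 and 0 in liver and 11, 3 and 4 in kidney.

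The replicate numbers were not taken to pair the samples, since the labels tie no numbers to animals and not every same-numbered pair of libraries correlated above 0.1. Such pairs averaged 0.13 in liver (-0.29 to 0.43, other pairs -0.02) and 0.17 in kidney (-0.41 to 0.63, other pairs -0.033), 10 of 16 in each exceeded 0.1, and 6 and 7 of 18 libraries matched their own number best. The averages lie above those of other pairs, so a grouping of the samples by number is not excluded. With the number as a block, liver ketogenic against control gave 81 genes, kidney high-fat against control 4 and kidney ketogenic against high-fat 3, while kidney ketogenic against control gave 55 (40 up, 15 down). Lists in liver high-fat against control went to 15, and the correlation of the diets' changes in kidney to 0.706.

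Correlations of the diets' changes over shared controls went from 0.705 to -0.0153 in liver and from 0.668 to 0.213 in kidney with the controls split, which removes the shared controls and leaves 2 or 3 controls per diet, and in kidney to 0.726 at a mean log2 CPM of at least 4. Liver and kidney changes correlated at 0.44 at that level and at 0.68 over called genes, all of them called in kidney only, against 0.169.

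Leaving out each library in turn gave 0 to 22, 0 to 1 and 0 to 0 genes in liver (without control 4 highest in the first), and 21 to 56, 2 to 3 and 2 to 10 in kidney. Lists ranged over 12 to 17, 7 to 22 and 10 to 20 in liver and 7 to 14 (7 without ketogenic 4), 4 to 16 (4 without high-fat 2) and 13 to 20 in kidney. The correlations ranged over 0.649 to 0.787 in liver, 0.604 to 0.738 in kidney and 0.0576 (without liver control 0) to 0.244 between tissues.

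Of 104 named results 99 kept their direction in every setting and 49 also their side of the threshold. The 5 that reversed were near 0. Without single libraries kidney Foxo3 ranged from -0.128 to 0.048, Ppargc1a from -0.136 to 0.045 and Bdh1 from -0.141 to 0.102, and liver Igfbp1 ranged from -0.161 to 0.391 and Foxo3 from -0.132 to 0.0061. The values above 0 for kidney Foxo3 were 0.0034, 0.0087, 0.0144 and 0.0481, for Ppargc1a 0.0026, 0.0057, 0.012, 0.0176, 0.0311 and 0.0451, and for Bdh1 0.0192, 0.0201, 0.0263, 0.041, 0.0556 and 0.102. Liver Igfbp1 fell below 0 without control 2 (-0.161) or ketogenic 0 (-0.13), and with limma-voom (-0.24). Kidney Ppargc1a was 0.00040 with the sample number, and Bdh1 0.039 with limma-voom and 0.157 with surrogate variables. Alternatives for values that are not counts were not run because counts were deposited. The median SE was 0.24 log2 units in liver against 0.169 in kidney for ketogenic against control. In the liver simulation 22.4% of 1.5-fold changes were recovered, against 79.1% of 2-fold changes, so most small changes would be missed. The simulated genes varied independently, those changed had a mean log2 CPM of at least 2, and no simulated library stood apart like control 0. These shares can thus overstate recovery in the real liver, where Scd1 at a log2 change of -2.93 did not pass.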

Other observations

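In this part the counts over other splits of the libraries were chosen as tests only after the results were seen, while the gene lists were fixed before. The 3 liver libraries with high interferon scores, control 0, high-fat 2 and high-fat 3, also had the highest cell cycle scores (1.89, 1.82 and 1.48, the other 15 at most -0.131) and the highest Nrf2 and glutathione scores (0.905, 0.542 and 0.988, others at most 0.265). Their kidney cell cycle scores were -0.0226, 0.288 and 0.249. Liver high-fat 5 had a PPAR alpha target score of -0.891 and a fatty acid synthesis score of 0.957, where the other 5 high-fat libraries had PPAR alpha target scores from -0.414 to 0.259. Liver ketogenic 6 had a fatty acid synthesis score of 0.425, with the other 6 ketogenic libraries between -0.649 and -0.382, and a PPAR alpha target score of 0.305, within their range of 0.251 to 0.597.

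Lists not described above gave these results for the ketogenic against the control diet in camera. In kidney, unfolded protein response genes were lower (median -0.12, adjusted p = 0.00246 preset, adjusted p = 0.584 estimated), as were heat shock genes (-0.14, adjusted p = 0.0179 preset, adjusted p = 0.584 estimated), lipoprotein genes (-0.19, adjusted p = 0.0429 preset, adjusted p = 0.57 estimated) and renin, angiotensin and sodium genes (-0.13, adjusted p = 0.0429 preset, adjusted p = 0.584 estimated). In liver, renal acid-base genes, which include Pck1, were higher (0.16, adjusted p = 0.0278 preset, adjusted p = 0.215 estimated), and stellate and fibroblast markers lower (-0.35, adjusted p = 0.0405 preset, adjusted p = 0.494 estimated). Liver lists that did not pass included insulin, IGF and FOXO genes (adjusted p = 0.54), the integrated stress response (0.926), the unfolded protein response (0.431), heat shock (0.306), the TCA cycle (0.15), Nrf2 and glutathione (0.227), xenobiotic metabolism (0.1), lipoproteins (0.926), acute phase (0.239), major urinary proteins (0.359), interferon response (0.694), cell cycle (0.147), oxidative phosphorylation (0.54), tubule injury and repair (0.905), renin, angiotensin and sodium genes (0.926), proximal tubule (0.905), glomerulus (0.54), macrophage (0.965), neutrophil (0.784), endothelial (0.54) and cholangiocyte markers (0.0568). In kidney, insulin, IGF and FOXO genes had an adjusted p of 0.262, the integrated stress response 0.317, the TCA cycle 0.896, oxidative phosphorylation 0.615, Nrf2 and glutathione 0.764, xenobiotic metabolism 0.908, the clock 0.375, macrophage markers 0.152, fibroblast markers 0.0518, endothelial markers 0.258, glomerulus markers 0.922, erythroid markers 0.406, acute phase genes 0.505, hepatocyte markers 0.922, proximal tubule markers 0.922, neutrophil markers 0.762, interferon response 0.428, cell cycle 0.263, tubule injury and repair 0.0518, bile acid genes 0.811, glycolysis 0.811, amino acid catabolism 0.762 and cholangiocyte markers 0.071. Pancreatic acinar, adrenal cortex and skeletal muscle markers had at most 1 tested gene in either tissue and were not tested, and neither were major urinary proteins in kidney nor loop to collecting duct markers in liver.

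In the liver, oxidative phosphorylation genes had a median of 0.20 on the ketogenic over the high-fat diet, with 43 of 44 above 0 (adjusted p = 4.16e-07 preset, adjusted p = 0.704 estimated). Ketogenic 0, 1 and 4 carried this, with scores of 0.406, 0.463 and 0.406, while the other 4 ketogenic libraries scored -0.29 to -0.168 and the high-fat libraries -0.526 to 0.21. Cholesterol synthesis genes were higher on the ketogenic than on the high-fat diet (0.19, adjusted p = 0.00019 preset, adjusted p = 0.652 estimated). Cholangiocyte markers were higher on the high-fat than on the control diet, all 6 above 0 (0.88, adjusted p = 0.00342 preset, adjusted p = 0.619 estimated), though high-fat 0 scored -0.92, against -0.979 to -0.171 in the controls.

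Splits of the same libraries into groups of the same sizes were counted, 100 per comparison, the real one included. For genes in kidney, 2 of 100 splits called at least as many as the real one in each of the 3 comparisons. For ketogenic against control the real count was 49 genes and the highest other 195. These counts were 2 and 22 for high-fat against control, and 7 and 8 for ketogenic against high-fat. Another split thus called more genes each time, and the shares were not adjusted over the comparisons, so chance is not excluded. The split with 195 genes set control 0, 1 and 3 with ketogenic 1 and 5 against the others, which points to a structure of the samples apart from diet, whose source was not tested. For genes in liver the real count is 0 in each comparison, so all 100 splits reach it by construction and the count says nothing about chance. The highest other counts there were 0 for ketogenic against control, 727 for high-fat against control and 0 for ketogenic against high-fat. The split of 727 genes set control 0, 1 and 3 with high-fat 1 and 3 against the rest. The 6 liver splits of high-fat and control that called 68 or more genes all put control 0 and high-fat 3 on the same side, as 45 of the 100 did, and the splits that parted them called at most 3. This points to a structure of the samples that involves these libraries, and its source was not tested.

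For lists called at the preset correlation, 3 of 100 splits had as many as the real 16 for ketogenic against control in liver. The highest other split had 20, and with an estimated correlation 0 of these lists passed, so chance is not excluded. Nor could chance be excluded for the other comparisons of lists at the preset correlation. In liver 82 of 100 splits had as many for high-fat against control (9, highest other 22) and 7 for ketogenic against high-fat (18, highest other 20). In kidney the numbers were 33 for ketogenic against control (12, highest other 22), 42 for high-fat against control (12, highest other 20) and 14 for ketogenic against high-fat (15, highest other 21). With an estimated correlation in kidney, 2 of 100 splits had as many as the real 2 lists for ketogenic against control (highest other 3). For ketogenic against high-fat 3 had as many as the real 1 (highest other 1). Other splits thus reached or passed the real counts, and the shares were not adjusted over the comparisons, so chance is not excluded. The other comparisons had 0 lists with an estimated correlation, which decides nothing.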
